A study of Homo sapiens with 52 samples.

How the data were processed

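Gene expression was measured in 52 human cell lines, given as breast lines in the sample titles, with 1 array of 2 colours for each line. Per the labels, cells were harvested before they were confluent, total RNA was purified on RNeasy columns, the RNA of the line was labelled with Cy5, and a common reference RNA was labelled with Cy3 by the Agilent Quick-Amp method. The reference was a mixture of equal amounts of RNA from 10 of the 52 lines, which were CAMA1, 184B5, MB175, MB361, MB157, DU4475, MCF7, MB231, MB468 and SKBR3. The labels gave no further grouping of the lines, so each line was treated as its own group, and membership of the mix was the only split of lines that was compared. No line had a replicate array, and the spread of a value between repeat cultures or repeat arrays of 1 line is unknown here.

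Deposited values of 2 kinds were used. The first was the scanner output of each array, with spot and background brightness as intensity on a linear scale, per the file headers. Per the file headers it was written by Agilent Feature Extraction 9.5.1.1 for 51 arrays and 10.7.3.1 for the array of UACC732, and the submitters' processing notes name Agilent Feature Extraction without a version. The software's own dye-normalized signals and its log10 ratio of Cy5 over Cy3 were also deposited in these files. The other was a table of all arrays, deposited as log10 ratio of Cy5 over Cy3. Its scale and direction were checked against the scanner output of each array, whose log10 ratio it repeated, and 5515 of its values were empty. It was not centred beyond the software's dye normalization, and for example the median of the CAMA1 column was 0.0253. The background code in the headers of 51 arrays was 7, which stands for no background subtraction, and the subtracted signal differed from the mean signal by a relative 5e-06 at most. The software's flag for a signal well above background was set for 100% of spots on every array. The filter on dim probes that had been planned with this flag removed no probe, and no filter, or the flag in Cy3 on all 52 arrays, gave identical values, so these were not run.

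Each array held 45015 spots, of which 1639 were controls and 153 of these were negative controls. The file of UACC732 holds no mean signal, and the software's subtracted signal, which was read for all arrays, was 1.01 times the median signal of the spot there in both channels (median over spots), with a local background of 0.0742 of it in Cy3 and 0.153 in Cy5, so that no subtraction is seen there either. In limma 3.58.1 (R 4.3.3) the spot signals were corrected for the local median background with normexp and an offset of 50, and log2 ratios were normalized within each array by loess, with control spots and spots with outlier marks given weight 0. Spots with outlier marks made up 0.258% to 0.996% of an array and were left out. For values of single channels, Aquantile normalization between arrays was added. Repeat spots were averaged, which left 41000 probes. For 264 probes with 10 repeat spots on an array, the SD of the log2 ratio among those spots was 0.0520 (median over probes and arrays). This is an error within 1 hybridisation only. A spot was called detected where its signal lay over the median of the negative controls by more than 5 robust SDs. This definition was chosen after the files had been examined, because the software's flag carried no information. Saturated spots were kept.

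Probes were named through the accession of the array design and a table of the GRCh38.p14 annotation, which was used for names only. By accession 23371 probes were named and by symbol or synonym 3348, 1650 kept the name in the files, and 12553 had no gene name and were left out. A further 78 probes of XIST, TSIX and Y-linked genes were left out. Coordinates are those of the array files, on build hg17, and mark the probe. Where in the transcript a probe lies was not worked out. For each gene the probe with the highest mean signal over both channels was kept, which gave 18790 genes, 18780 of them with values on all arrays. Of these, 7119 genes had more than 1 probe. In 5353 genes a second probe was detected, its r with the kept probe over lines had a median of 0.814, and it lay under 0.5 for 959 genes. The kept probe was detected in the reference channel on at least 26 arrays for 15085 genes and on none for 963. Ratios to an undetected reference are bounds.

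Median Cy5 signal per array ranged from 261.74 to 727.71 (median 473.02) and median Cy3 signal from 200.93 to 315.53 (median 231.3). Between 58.9% and 78.2% of probes were detected in Cy5 and between 67.1% and 79.3% in Cy3. The negative controls had a median signal of 82.6 in Cy5 and 53.6 in Cy3. Saturated spots in Cy5 numbered 1132 on the array of MB175, 894 on that of MB231 and 559 on that of MB330, which shared a scanner, against a median of 12.5. In Cy3, 449 spots were saturated on the array of MB175, against a median of 0. The arrays lay on 20 slides, of which 14 held more than 1 array, were scanned on 10 days, with 12, 10 and 17 arrays on the 3 largest days, and were read by 3 scanners, 46 of them by the same one. The title of the UACC732 sample names another preparation of the reference than the other titles do. The number of arrays, 1 per line, limits the precision of every value of a single line.

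The tests, the genes to be named, 26 gene lists with 390 entries, 58 gene pairs and most alternative settings were chosen before the data were examined. Of the list entries 383 were measured, and KRT6A, PVT1, MAGEA3, CTAG1B, XAGE1A, CD24 and HIST1H2BC were not, so that 57 pairs remained. Named genes were 14 fixed markers, the 12 genes with the largest SD between lines, the 3 most variable and the least variable member of each list, 8 genes at each end of the first 2 principal components, the 12 genes with the largest gap of 1 line to the next (at most 2 per line), the genes of the pairs, and the 3 genes with the highest and the lowest mean ratio in the lines of the mix. Genes named outside that rule are marked as such.

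Variation between lines was compared with measurement variation by the Pitman-Morgan test of equal variance of the paired Cy5 and Cy3 signals, two-sided, adjusted by Benjamini-Hochberg over all genes at a threshold of 0.05, with 100 random swaps of the channels within arrays as a null. On simulated data for 18790 genes the test recovered 20% of 50 genes with an SD ratio of 1.5, 98% of 50 with a ratio of 2 and 100% of 50 with a ratio of 3, and it called 0.0269% of 18590 unchanged genes. Both simulated channels had equal noise. On the arrays 72.0% of the genes detected in neither channel passed, so that the simulated rate of false calls does not carry over to them. A pair was tested by Pearson's r and Spearman's rho over lines, each with a two-sided permutation p from 100000 resamples, for which 1e-05 is the smallest possible value, and adjusted over the 86 tests of the family. Where the first gene of a pair, or else the second, split the lines into clusters (mclust 6.1.1, 2 components of equal variance, BIC gain over 10, means over 3 SD apart), only values within clusters of at least 6 lines were computed. In 20 tests the other gene split the lines as well. Of these 7 passed, 6 of them over lines of both its clusters, and values within its larger cluster were computed afterwards. The mean pairwise r of each list was set against 10000 random lists of equal size matched on signal in 10 bins, and the list's median ratio in each line against the same random lists. Principal components were computed on the 2000 most variable genes, with an SD from 100 bootstrap draws of lines. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

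Alternatives were the scanner software's own normalization, median centring in place of loess, a normexp offset of 16, the mean of a gene's probes, the deposited table of log10 ratios, arrays left out by scanner or reference preparation, slide means removed, no normalization between arrays, Gquantile in place of Aquantile, Spearman's rho for lists and for similarity, the median over lines of the mix, the omission of MB435, and other numbers of genes, gaps and folds. Detected probes only, probes detected in Cy3 on all arrays, scan day means removed and the omission of DU4475 were added after the data had been seen. Where slide means were removed, arrays alone on their slide among the lines used were left out.

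An item withheld for evaluation is not reported here.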

Results

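RNA of 52 human cell lines, most of them established from breast cancers and a few from non-malignant breast epithelium, was measured on 2-colour oligonucleotide arrays. The tissue of origin of single lines was not checked. That holds for MB435 too, whose melanocyte list median (2.13) lay far above that of the other lines. The Cy5 channel of each array held the RNA of 1 line and the Cy3 channel held a reference mixed from equal amounts of RNA of 10 of these lines. Values are log2 ratios of a line over the reference mix unless stated otherwise, so that 0 marks the mean level of the mix. There was 1 array per line and no replicate, so a value of a single line carries no error of its own and the spread given is that over lines. The kept probe was detected in both channels on at least 26 arrays for 14286 genes. A saturated Cy5 spot gives too low a ratio, and a saturated Cy3 spot gives too high a ratio. Saturation in Cy3 was not followed for single genes. No line named below as the highest for a gene had a saturated Cy5 spot for it, but others did in 2 lines each for CDH1, VIM and FOXA1 and in 1 each for PIP, AUTS2, CAV1, CD44 and TACSTD2, so that these maxima hold among unsaturated lines.

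Single genes differed widely between the lines. PIP, a secreted protein of apocrine cells, had the largest SD of the Cy5 signal over the 52 lines, 3.18 on the log2 scale, and ranged from 5.07 in SUM190 to 74.1-fold below the reference in COLO824. It was followed by the homeobox gene HOXB2 (SD 3.08), the ubiquitin hydrolase gene UCHL1 (3.05), the chemokine gene CXCL14 (2.92), the adhesion receptor gene ADGRF1 (2.92) and the tumour antigen gene PRAME (2.88). KRT23, ALDH1A3, AUTS2, ELAPOR1, ACKR3 and CEACAM6 completed the 12 most variable genes, with SDs from 2.85 to 2.77. ACKR3 stood 8.22-fold above the reference in KPL1 and 178-fold below it in HCC1187, and AUTS2 was 8.03-fold above it in SUM190 and 125-fold below it in JIMT1.

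Among the 14 markers fixed in advance, ESR1 (oestrogen receptor alpha, probe on chromosome 6 from 152516022 to 152516081, hg17) had an SD of 2.31 between lines against 0.287 in the reference channel. It was highest in MB330 (3.14), MB134 (2.97) and EFM19 (2.81), stood at least 4-fold above the reference in 7 lines and at least 4-fold below it in 23, and was detected in 39 lines. PGR, the progesterone receptor, was detected in 16 lines and was highest in EFM19 (3.49), BT474 (3.41) and T47D (3.37). ERBB2, the HER2 receptor gene (chromosome 17 from 35138355 to 35138414), stood at least 4-fold above the reference in 8 lines and was 19.7-fold below it in DU4475. Its Cy5 spot was saturated in 11 lines, so that its highest values are not ordered here, and its SD in the reference channel was 0.846, larger than for most genes. EGFR was highest in MB468 (1.64) and at least 4-fold below the reference in 24 lines. CDH1, E-cadherin (chromosome 16 from 67426715 to 67426774), reached 2.54 in ZR751 and was 36.4-fold below the reference in MB436, and VIM, vimentin, reached 3.06 in Hs578T and was 17.9-fold below the reference in EFM19. GATA3 ranged from 2.22 in EFM19 to -2.24 in COLO824, and KRT5 was highest in MCF12A (2.11) and MCF10A (1.82).

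Genes of cell cycle control showed wide ranges as well. RB1, the retinoblastoma gene (chromosome 13 from 47953846 to 47953905), was 67.1-fold below the reference in COLO824 and fell into a cluster of 47 lines with a mean of -0.53 ± 0.86 (SD) and a cluster of 5 lines, BT549, COLO824, DU4475, HCC2157 and MB468, with a mean of -4.99 ± 0.99. CDKN2A was highest in BT549 (2.60) and HCC70 (2.45) and lowest in MB231 (-2.61). PTEN was 8.35-fold below the reference in HCC38 and reached 2.27 in MCF10A. CCND1, cyclin D1, reached 2.97 in MB134 and 2.36 in HCC1954 and was 54.3-fold below the reference in COLO824. FGFR1 was highest in HCC1187 (2.74) and MYC in HCC1143 (2.10).

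Of 18780 genes tested, 18129 (96.5%) were more variable between lines than the reference RNA was between arrays, and 24 were more variable in the reference channel (Pitman-Morgan test, Benjamini-Hochberg adjusted). In random swaps of the channels a median of 2076 genes and at most 8455 passed. Among the 14286 detected genes 14131 (98.9%) passed, with a median SD of 0.721 in the lines and 0.184 in the reference. The test by itself did not isolate expression differences, because 327 of 454 genes (72.0%) detected in neither channel on any array passed too, with a median SD ratio of 1.34 and a 95th percentile of 1.76. The ratio of the detected genes had a median of 3.91 and lay over that percentile for 13442 of them (94.1%), and 3738 detected genes had an SD of at least 1 between lines and 283 an SD of at least 2.

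**Figure D1:**
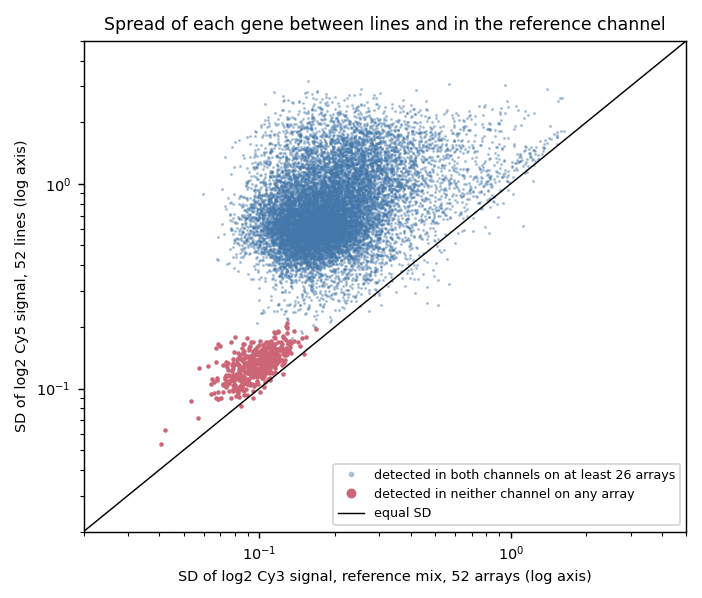
SD of the normalized log2 Cy5 signal over 52 lines against the SD of the log2 Cy3 signal of the reference over the same 52 arrays, both on log axes, 1 point per gene. Genes detected in both channels on at least 26 arrays (median SD 0.721 against 0.184) lie mostly far above the line of equal SD, and the 454 genes detected in neither channel lie close to it.

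Groups of functionally related genes rose and fell together over the lines. The 26 lists fixed in advance were scored by the mean r of their members over lines, set against random lists of the same size and signal, and 21 lay over the 95th percentile of those. Interferon response genes moved most closely together (mean pairwise r 0.735), followed by histone genes (0.683), genes of MHC class II presentation (0.619), epithelial adhesion genes (0.614), the 17q23 region (0.599) and proliferation genes (0.586). For each list the number of members more variable in the lines than in the reference was the same adjusted over all genes and adjusted over the list alone, so that 1 count is given for both. Of all genes tested 96.5% passed, so that a count near the size of its list does not set that list apart.

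Luminal and oestrogen receptor genes (mean pairwise r 0.476) were more variable in the lines for 23 of 25 members. The list median was highest in UACC732 (1.1), ZR751 (1.01) and HCC1500 (0.93) and lowest in COLO824 (-2.68) and JIMT1 (-2.65). FOXA1, a transcription factor that opens chromatin for the oestrogen receptor, reached 2.72 in MB453 and was 60.0-fold below the reference in MB231, and AR, the androgen receptor, reached 3.33 in MB453 and was 36.8-fold below it in COLO824. KRT18 was saturated in 5 lines and did not pass (adjusted p = 0.769). Basal epithelial genes (0.487; 23 of 23) had their highest medians in MCF12A (2.10), MCF10A (1.80), 184A1 (1.46) and 184B5 (1.28) and their lowest in CAMA1 (-2.71). TP63, a regulator of basal epithelium, followed this order with 3.03 in MCF12A and 2.94 in MCF10A, CAV1 was highest in Hs578T (2.56), and MET was 108-fold below the reference in DU4475. Apocrine and androgen receptor genes (0.210; 14 of 15) were highest in SUM190 (1.68) and SUM225 (1.26) and lowest in JIMT1 (-1.94), and TFAP2B was 86.1-fold below the reference in COLO824.

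Epithelial adhesion genes (20 of 20 more variable in the lines) had a list median of 0.94 in EFM192A and were lowest in MB436 (-2.37), MB231 (-2.37), HCC1395 (-2.34) and Hs578T (-2.09). The tight junction gene CLDN3 reached 2.62 in SUM225 and TACSTD2 3.41 in HCC1143. Mesenchymal genes (0.449; 24 of 24) were highest in Hs578T (2.43), MB157 (1.83) and BT549 (0.95) and lowest in EFM19 (-2.30). The collagen-crosslinking enzyme LOX reached 4.80 in Hs578T and was detected in 29 lines, and SNAI2, a repressor of E-cadherin, reached 2.49 in Hs578T and was 52.7-fold below the reference in HCC1187. ZEB1, the least variable member, was detected in 9 lines and reached 1.81 in MB231. Claudin-low and stem-like genes (0.219; 9 of 9) were highest in JIMT1 (1.29) and Hs578T (0.88) and lowest in CAMA1 (-2.76), with the hyaluronan receptor CD44 at 3.03 in HCC1806 and 54.4-fold below the reference in DU4475.

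Neighbouring genes of chromosome regions that are often gained in breast cancer were also expressed together, although copy number was not measured. The 14 genes around ERBB2 on 17q12 (0.50; 14 of 14) had medians of 2.18 in EFM192A and 1.75 each in BT474 and UACC893, and PGAP3 reached 3.36 in EFM192A. The 11q13 genes around CCND1 (0.242; 10 of 10) were highest in MB415 (1.58), MB330 (1.53) and MB134 (1.07), the 8p11 genes around FGFR1 (0.429; 16 of 16) in JIMT1 (1.89), MB134 (1.73) and MB330 (1.26), and the 17q23 genes (11 of 11) in KPL1 (1.92) and MCF7 (1.88), where TBX2 stood at 2.65 and 3.12. RAB11FIP1 on 8p11 reached 4.77 in SUM225. The 20q13 genes (0.354; 11 of 11) were highest in BT474 (1.28) and lowest in DU4475 (-1.42). The 8q24 genes around MYC (0.176; 7 of 7) were highest in HCC1806 (1.29) and lay at the 99.66th percentile of random lists. Tumour suppressor genes were each more variable in the lines (15 of 15), but the list as a whole did not stand out from random lists (mean pairwise r 0.0237, percentile 86.4), with list medians from -0.82 in MB453 to 0.68 in KPL1.

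Immune and growth programmes varied too. The interferon response (20 of 20) had medians of 2.26 in HCC1143 and 2.21 in BT549 and of -2.95 in COLO824, and IFI44L, its most variable gene, ranged from 3.25 in HCC1187 to 17.8-fold below the reference in COLO824. MHC class II genes (10 of 10) were highest in MB435 (2.33), HCC1143 (1.5) and HCC70 (1.38) and lowest in JIMT1 (-1.99). Proliferation genes (20 of 20) were lowest in MCF10A (-2.5), 184A1 (-1.98) and CAMA1 (-1.94) and highest in MB231 (0.54), and UBE2C was 28.9-fold below the reference in MCF10A. With slide means removed the value of MB231 was -0.0027. MB330 was the only other line on that slide, so that this value rests on their difference and shows no slide effect. Histone genes (9 of 9) were highest in MB330 (1.43), UACC732 (1.26) and HCC202 (1.21) and lowest in CAL51 (-1.78) and MB436 (-1.36). Cancer testis genes (0.301; 12 of 12) were highest in MB435 (0.78) and SKBR3 (0.68) and lowest in UACC812 (-1.97), and PRAME reached 4.31 in HCC1187.

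Metabolic and stress programmes varied as well. Hypoxia genes (0.167; 15 of 15) were highest in MB361 (1.47) and lowest in T47D (-1.02), with the oxygen sensor EGLN3 at 3.51 in MB453. Sterol synthesis genes (0.404; 16 of 16) were highest in UACC812 (1.34) and lowest in CAMA1 (-1.13). Genes of the unfolded protein and amino acid response (0.289; 15 of 15) were highest in MB453 (1.54) and lowest in MCF10A (-1.47), with ATF3 at 3.51 in MB453.

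Lists of other cell types had medians near 0 apart from the melanocyte list, although single members varied, such as LCP1 and ARHGDIB of the blood cell list with an SD of 2.10 each. Only 7 of 15 blood cell genes, 3 of 10 endothelial genes and 6 of 10 adipocyte genes were detected in at least 26 lines, so that medians near 0 do not show equal expression. Blood cell genes (mean pairwise r 0.0109, percentile 68.8; 14 of 15) had medians between -0.12 and 0.19, endothelial genes (-0.0273, percentile 7.95; 9 of 10) between -0.24 and 0.22, and adipocyte genes (0.0110, percentile 64.3; 8 of 10) between -0.16 and 0.31. Melanocyte genes (0.220; 16 of 16), of which 8 were detected in at least 26 lines, had a median of 2.13 in MB435 and of 0.24 in the next line, 184A1. The coherence of that list fell to -0.02 when only genes detected in the reference on all arrays were kept. MB435 is not part of the mix, so that this filter leaves out members that the mix lacks. The fall thus says nothing for or against the list in MB435. Housekeeping genes (-0.0076, percentile 19.8; 11 of 15) had medians between -0.29 in HCC1419 and 0.60 in UACC812, with B2M 19.2-fold below the reference in MB157. Over all lists and lines, 659 list medians lay outside the central 95% of random lists.

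**Figure D2:**
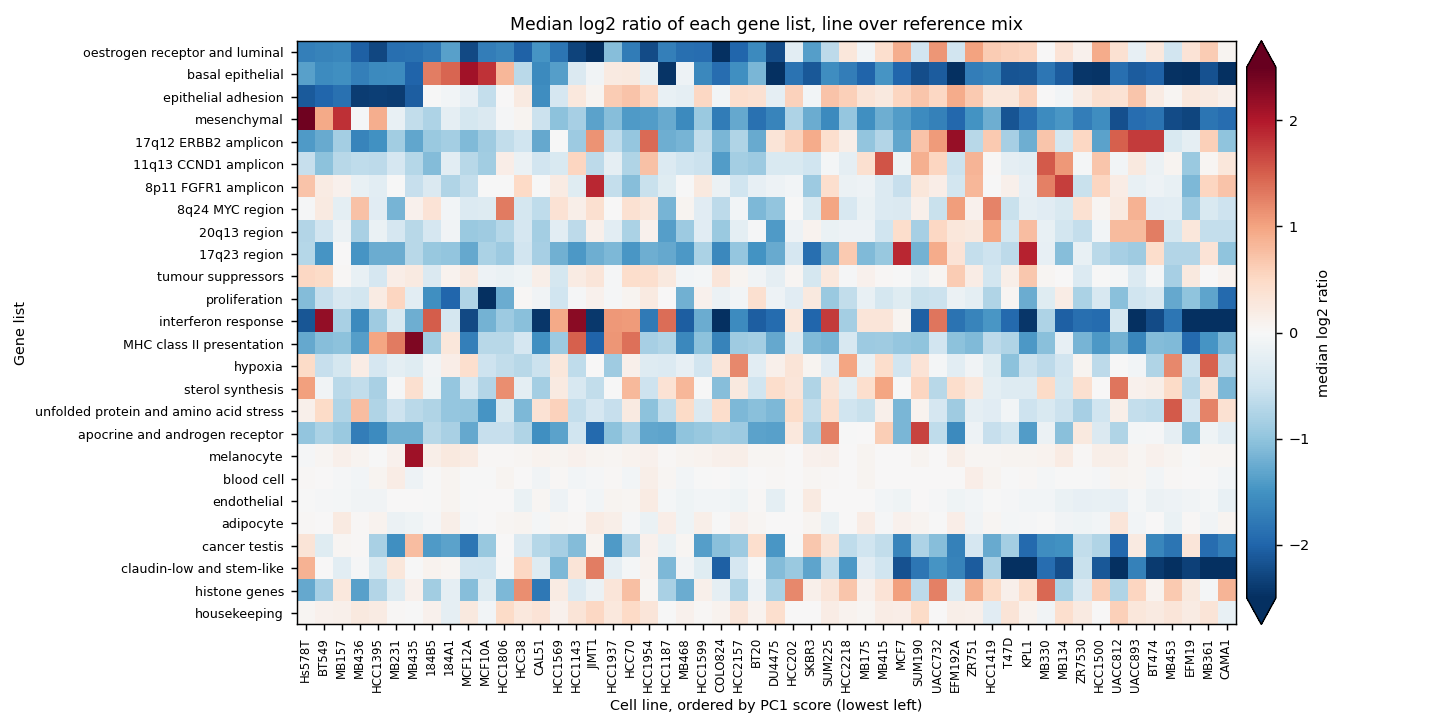
Median log2 ratio over the reference of each of the 26 gene lists (rows of the map) in each of the 52 lines (columns, ordered by their score on the first principal component), blue below and red above the reference. Luminal and epithelial adhesion lists are higher towards the right and mesenchymal, basal and claudin-low lists towards the left, and the melanocyte list is near 0 except in MB435 (2.13).

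ESR1 rose with GATA3 and with some of the other luminal genes tested. ESR1 and GATA3 were positively related over the 52 lines, with r = 0.678 and rho = 0.678 (permutation p = 1e-05 for both, the smallest possible, adjusted p 0.000143 and 0.000172). Without the 2 lines farthest from the median of ESR1 r was 0.676, with slide means removed 0.674, and within the 3 largest scan days 0.881, 0.843 and 0.385. ESR1 was also related to MYB (r = 0.559, adjusted permutation p = 0.000235) and KRT18 (r = 0.514, adjusted permutation p = 0.00043). KRT18 was saturated in 5 lines and was not more variable in the lines than in the reference (Pitman-Morgan test, adjusted p = 0.769). FOXA1 split the lines into 31 with higher and 21 with lower levels, and ESR1 followed it within the higher cluster (r = 0.491, adjusted permutation p = 0.0151), though not by rho (0.365, adjusted p 0.0930), and did not pass in the lower one (r = 0.225), a difference between clusters that was not tested. PGR, TFF1, XBP1, GREB1 and AR split the lines likewise, and of their 10 tests with ESR1 only PGR in the lower cluster of 42 lines (r = 0.364), TFF1 in the lower cluster of 43 lines (r = 0.347) and GREB1 in the higher cluster of 16 lines (r = 0.620) passed, none of them by rho. PGR was detected in 16 of the 52 lines, so that most of the 42 lines held no detected PGR signal. The relation with GREB1 rested on the 2 farthest lines, since r was 0.0370 without them. ESR1 and EGFR, with r = -0.292, did not pass (adjusted permutation p = 0.0733).

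E-cadherin and vimentin were inversely related over the 52 lines (r = -0.550, permutation p = 5e-05, rho = -0.443, permutation p = 0.00103, adjusted p 0.000331 and 0.00385). The value was -0.494 without the 2 farthest lines, -0.607 with slide means removed, and -0.745, -0.505 and -0.595 within the 3 largest scan days. CDH1 rose with the junction genes CLDN7 (r = 0.605) and CLDN4 (r = 0.578) and with the epithelial factor ELF3 (r = 0.546), and fell with SNAI2 (r = -0.346), with adjusted permutation p of 0.000235, 0.000287, 0.000235 and 0.0301. Within the 10 lines with low EPCAM, CDH1 and EPCAM had r = 0.925 (adjusted permutation p = 0.00168), and in the other 42 lines the pair did not pass (r = 0.325). CDH1 with ZEB1 passed in the 46 lines of lower ZEB1 (r = -0.486), though not by rho. ZEB1 was detected in 9 of the 52 lines, so that most of these 46 lines held no detected ZEB1 signal. With ZEB2, ESRP1 and GRHL2, CDH1 passed in no cluster by r. By rho it passed with ESRP1 in the 44 lines of higher ESRP1 (rho = 0.386, adjusted permutation p = 0.0283), where r was 0.281.

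ERBB2 split the lines into 16 with higher values and 36 with a mean of -2.65 ± 0.87 (SD). The higher cluster held UACC812, MB361, UACC893, SUM225, SUM190, UACC732, BT474, EFM192A, HCC1419, HCC1569, HCC1954, HCC202, HCC2218, SKBR3, ZR7530 and MB330. Its Cy5 spot was saturated in 10 of these 16 lines, so that the order of ERBB2 among them is not known and no relation is read from the tests within that cluster, of which those with GRB7, MIEN1 and PGAP3 passed. Within the lower cluster, with 1 saturated line, ERBB2 rose with PGAP3 (r = 0.561), MED1 (r = 0.488) and PSMD3 (r = 0.453). These genes split the lines as well, and without EFM19, JIMT1 and JIMT1, which lie in their higher clusters, r was 0.617, 0.464 and 0.434. GRB7 there had r = 0.277 and did not pass (adjusted permutation p = 0.187). STARD3 (r = -0.0309), MIEN1 (r = 0.264) and CDK12 (r = 0.220) did not pass there either. Without DU4475 and JIMT1, which lie in the higher clusters of STARD3 and MIEN1, their r was 0.228 and 0.422, and without JIMT1 that of CDK12 was 0.0761.

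The genes of the CDKN2A locus were expressed together, with r = 0.642 for CDKN2B and 0.619 for MTAP (adjusted permutation p = 0.000143 for both). Within the 47 lines of higher RB1, CDKN2A was inversely related to RB1 (r = -0.479, permutation p = 0.00064, rho = -0.494, permutation p = 0.00052, adjusted p 0.00239 and 0.00235). That value was -0.432 without the 2 farthest lines, -0.519 with slide means removed, and -0.709, -0.316 and -0.626 within the 3 largest scan days. The 5 lines of low RB1 were too few to test. CDKN2A also rose with CCNE1, cyclin E1 (r = 0.423, adjusted permutation p = 0.00542). Neighbours on 8p11 and 11q13 moved with FGFR1 and CCND1, with r = 0.604 for FGFR1 and LSM1, 0.598 for FGFR1 and ASH2L, 0.561 for CCND1 and LTO1, and 0.557 for CCND1 and CTTN. In scan day 2 the values of CCND1 with LTO1 and CTTN were 0.0796 and 0.00356. Of the cell cycle genes, AURKA rose with UBE2C (r = 0.727) and TOP2A (r = 0.511), and MKI67 did not pass (r = 0.218, adjusted permutation p = 0.210). TP53 was related to neither of its target genes CDKN1A (r = 0.195) and MDM2 (r = 0.121) at the threshold.

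In all, 57 pairs gave 86 tests, 26 over all lines and the others within clusters, and 39 passed, 34 with a positive and 5 with a negative sign. The 3 within the higher ERBB2 cluster are among them, and 36 were left without these. The 22 that passed over all lines had the same sign in each of the 3 largest scan days. Of those that passed within clusters, 11 had a value in the third scan day and 10 kept their sign there. By Spearman's rho 30 of the 39 also passed. Under other processing 31 passed wherever they were tested and 8 lost the call at least once, namely ESR1 with FOXA1, PGR, TFF1 and GREB1, ERBB2 with PSMD3, KRT5 with KRT14 and KRT18, and ZNF217 with PFDN4. By Pearson's r, KRT5 with KRT14 and with KRT18 passed only within the 12 lines of higher KRT5 (r = 0.649 and -0.677). By rho neither passed there, and KRT5 with KRT14 passed within the 40 lines of lower KRT5 (rho = 0.548, adjusted p 0.00192), where r was 0.210 and turned to -0.223 with slide means removed. KRT14 splits the lines as well, and within its lower cluster r was -0.363 in 8 of the 12 lines and 0.536 (rho = 0.653) in 38 of the 40, computed afterwards. The r of 0.649 rested on the 2 farthest lines, with -0.0116 without them. With slide means removed, that of -0.677 turned to 0.196. Of the 12 lines, only 184A1, 184B5, MCF10A, MCF12A, HCC38 and HCC70 shared a slide with another and entered that value. A value over so few lines does not show a slide effect.

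**Figure D3:**
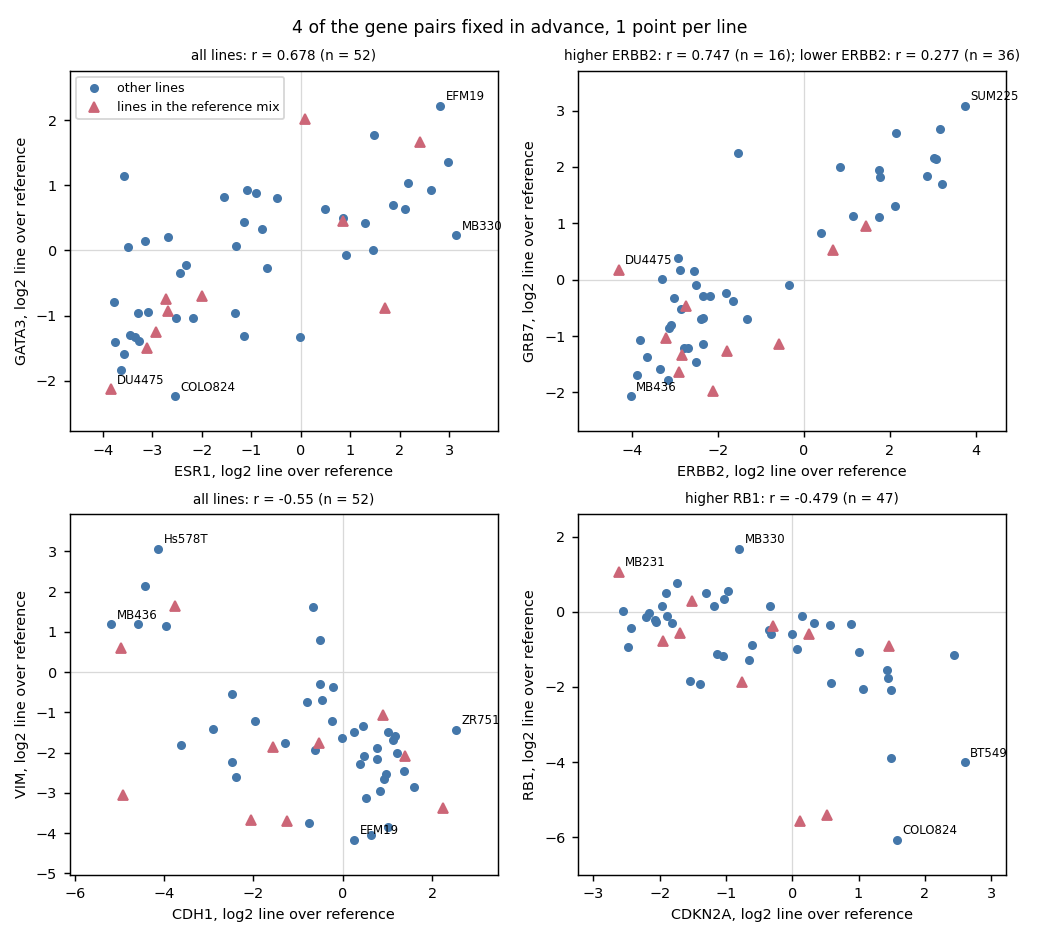
Log2 ratios over the reference of 4 gene pairs, 1 point per line, with triangles for the 10 lines of the reference mix. ESR1 and GATA3 rise together (r = 0.678), ERBB2 and GRB7 separate 16 lines of high ERBB2 from 36 others, CDH1 and VIM are inversely related (r = -0.550), and CDKN2A and RB1 are inversely related among 47 lines (r = -0.479), below which lie 5 lines of low RB1.

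The main axis of variation ran from mesenchymal to luminal lines. The first principal component of the 2000 most variable genes held 18.6% ± 1.85 (bootstrap SD over lines) of the variance. Its positive end was led by TTC39A (r = 0.891), FOXA1 (0.885), GPR160 (0.879) and CREB3L4 (0.872), with PRR15L, MYO5C, SIDT1 and XBP1 next. Its negative end was led by KIRREL1 (-0.884), the membrane linker MSN (-0.876) and the caveolar gene CAV1 (-0.841). AKR1B1, FOXF2, the caveolar gene CAVIN1 (-0.818), RGS20 and P3H2 came next there. CAMA1, MB361 and EFM19 had the highest scores, and Hs578T had the lowest. Members of the luminal list had a median r of 0.588 with the component, epithelial adhesion genes 0.565 and histone genes 0.490, against -0.562 for mesenchymal, -0.457 for claudin-low and -0.411 for basal genes. These lists all lay outside the central 95% of random lists.

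The second component, with 7.86% ± 1.38, had basal and epithelial adhesion genes towards its negative end. Its negative end was led by ADGRF1 (-0.794), the epithelial factor ELF3 (-0.791), DAPP1 and the protease inhibitor SLPI (-0.781), with FXYD3, STEAP4 and S100P among the next, and its positive end by MMP16 (0.662), ARNT2 (0.636) and REEP2 (0.623), followed by ATP8B2, ANXA6, PDZRN3, MLLT11 and DACT3. Basal genes (median r -0.511), epithelial adhesion genes (-0.410) and interferon response genes (-0.289) lay towards the negative end and mesenchymal genes (0.249) and 8p11 genes (0.267) towards the positive end. Computed on all genes, the scores of the second component had r = 0.673 with those given here.

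**Figure D4:**
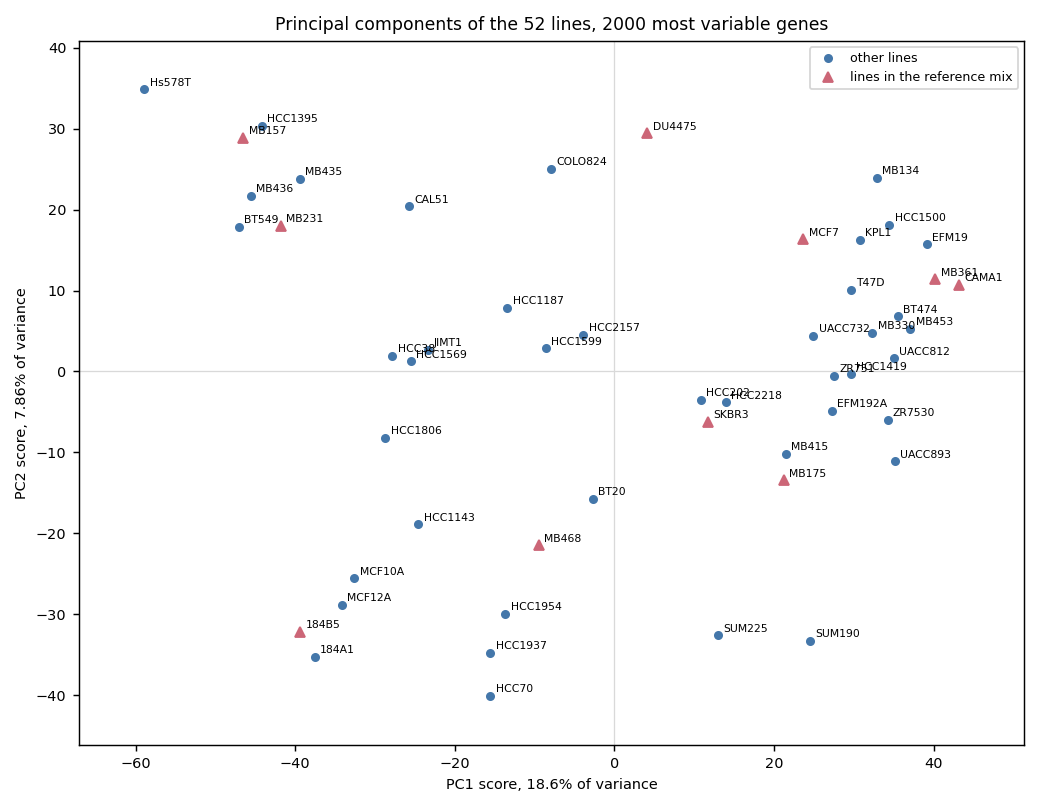
Scores of the 52 lines on the first component (18.6% of variance) and the second component (7.86%), with triangles for the 10 lines of the reference mix. Hs578T lies at the left end and CAMA1 at the right end, and the 4 lines with the highest basal list medians (MCF12A, MCF10A, 184A1 and 184B5) lie together at the lower left.

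Some genes were expressed at a far higher ratio in 1 line than in any other. In 306 genes the highest line exceeded the next by at least 2 on the log2 scale and was detected there. In the reference channel 129 genes had such a gap, counted in the Cy3 signal without a detection filter. For 128 of these the Cy5 signal was highest on the same array, so that this count is not free of differences between lines. DU4475 held 123 of the 306, followed by MB435 with 18, MB157 with 12, HCC1500 with 11 and Hs578T with 10, and without DU4475 the count was 194. In DU4475 the glutamate receptor gene GRM8 stood at 3.07 and the next line at -2.63, and the homeobox gene PROX1 stood at 4.85 and was not detected in the next line. TAT, tyrosine aminotransferase, reached 2.96 in MB361, PRKCB 5.12 in MB436, SPINK13 5.58 in T47D, SEC61G 3.81 in MB468, FLG, filaggrin, 4.18 in MB231, SPRR1B 4.96 in MCF12A and SPHKAP 3.60 in MB157. OR51E2 was at least 31.9-fold above the reference in MB157, where the reference was not detected. PRKCB was detected in 1 line and FLG in 2.

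For the 2 other genes that the rule named, the gap lay in the background-corrected reference signal. CHD1L, with the largest gap (7.12 in HCC2218, next line 1.37), and PAXIP1 (5.12 in HCC202, next line 0.94) did not have their highest Cy5 signal in those lines, and their Cy3 signal there differed from the median of the other arrays by -6.40 and -8.01 on the log2 scale. The scanner software, which subtracts no background, gave 1.17 and 0.52 for them, under the next lines. The same held for TMEM143 in BT549, named here after its values were seen, and the other 303 genes had their highest Cy5 signal in the line concerned. Of the 306 genes 273 were also set apart in the scanner software's ratios, and the count was 164 with slide means removed and 180 among genes detected in the reference on all arrays.

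The mean ratio over the 10 lines of the mix would be 1 for each gene if the parts were equal, but normalization centres each array and undetected genes lie near 1 as well, so that the share near 1 does not test this. For 72.2% of 18780 genes (95% Wilson interval 71.5 to 72.8, over genes, which are not independent) the mean lay between 0.8 and its inverse, with 8.23% under and 19.6% over that range and a median of 1.07. With median centring in place of loess the share was 45.1%. TCN1, a vitamin B12 carrier, had the lowest mean (0.0822), followed by RGS22 (0.148) and LOC57400 (0.161, detected in no line). The highest ratio in any line of the mix was 0.262 for TCN1 (MB361) and 0.405 for RGS22 (MCF7). Unequal parts alone do not give a ratio under 1 in every line of the mix. These genes are extremes of all genes, and the cause was not tested. The extracellular matrix gene LUM (4.73), the immediate early gene EGR1 (4.55) and CFHR1 (4.47) had the highest means. A part of the mix cannot exceed 10 times the mix if amounts are equal, and 174 of 187800 ratios did, in 170 genes. DU4475 held 78 of them and MB157 42, and the highest was 42.7, for LUM in MB157. The count was 96 without DU4475 and 386 with median centring.

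Lines of the mix were not measurably closer to the reference than other lines. The number of genes at least 4-fold from it was 971.8 ± 374 (SD, n = 10) for lines of the mix and 955.7 ± 312 (SD, n = 42) for the others, a difference of 16.1 (two-sided permutation test, p = 0.889). Within the 4 scan days that held both kinds of lines the differences were 379.9, -136.5, -183 and -37, each over few lines, and the pooled difference turned to -89.1 without DU4475, -94.3 with scan day means removed and -66.6 with the scanner software's ratios. At 2-fold the means were 3729.2 ± 770 and 3586.2 ± 764 (permutation p = 0.594). DU4475 had the highest count (1919) and HCC202 the lowest (223), with a median of 959 over lines. For 6 lines the count depended strongly on the processing, since the scanner software's ratios, which rest on another background handling and another dye normalization, gave 2.99 times as many genes in HCC202, 2.62 in HCC2218, 2.34 in UACC732, 1.96 in MCF10A, 1.82 in HCC1806 and 1.65 in BT549. The lowest count by those ratios was 550, in ZR751, and the highest was again in DU4475 (1875).

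**Figure D5:**
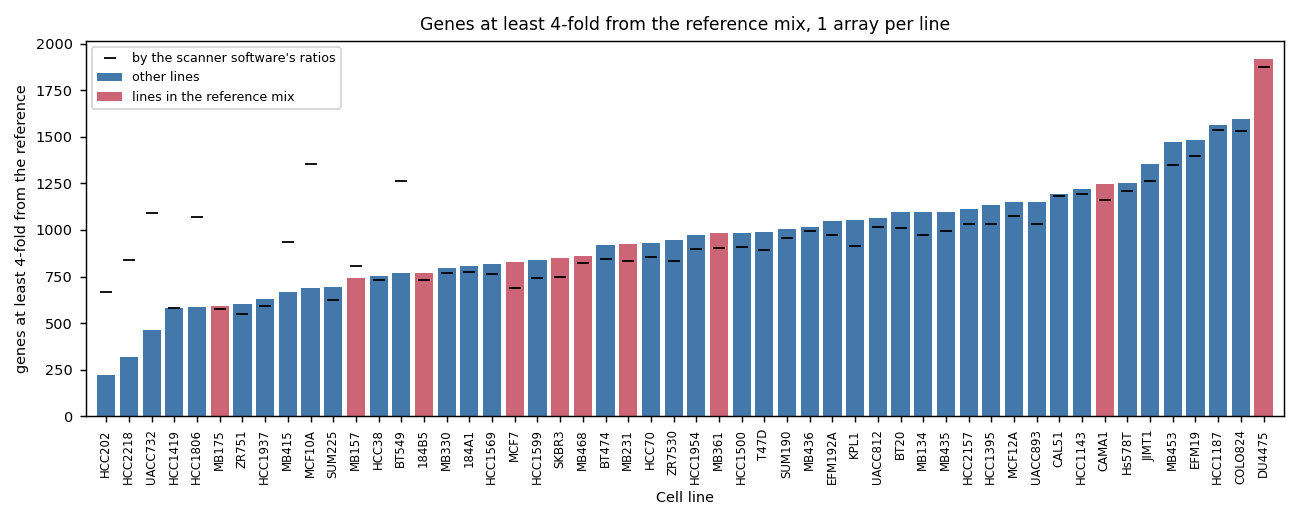
Number of genes at least 4-fold from the reference in each of the 52 lines, with lines of the reference mix in red and the count from the scanner software's own ratios as a dash. Counts run from 223 in HCC202 to 1919 in DU4475, and the dash lies far above the bar for 6 lines, among them HCC202, HCC2218 and UACC732.

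Lines resembled each other in a few close pairs. Across the 2000 most variable genes, which are not independent replicates, the 1326 pairs of lines had a median r of -0.0486, and the r of a line to its nearest line had a median of 0.388. The closest were MCF10A with MCF12A (0.679), 184A1 with 184B5 (0.679), KPL1 with MCF7 (0.660), MB157 with Hs578T (0.606) and HCC1395 with Hs578T (0.593), and 16 pairs were each other's nearest. The 2 closest pairs each shared a slide, and KPL1 and MCF7 did not. The permutation tests over lines treat all lines as independent, which lines this alike may not be. DU4475 had the lowest r to its nearest line, 0.0921. For 5 lines, among them the 4 of the 2 closest pairs, the nearest was on the same slide, against 2.22 expected with permuted slides (permutation p = 0.115). Of the variance of a gene 31.2% lay between slides (median over genes), against 28.1% with permuted slides and at most 31.16% in 100 permutations (permutation p = 0.0099, the smallest possible). Because the 2 closest pairs shared slides, an effect of slides cannot be told apart from likeness of the lines placed on them.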

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

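The tests of normalization and of Cy5 light in the Cy3 channel, and of slide or scan day for the histone genes, were chosen after the result was seen, and so were the spread conditions on the amounts and cultures in the mix. Values that stand apart from the other lines of a group of 10 are given first, and chance alone would single out about 1 in 20 such groups.

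DU4475 stood apart from the other 9 lines of the reference mix in each of 3 counts that share the same ratios. It had 1919 genes at least 4-fold from the reference, and the next line of the mix had 1245. At 2-fold it had 5704 genes, and the next line had 4229. It had 78 ratios over 10, and the next line, MB157, had 42.

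Ratios over 10 cannot arise in a line that is 1 of 10 equal parts of the mix, and 174 were seen. A reference too dim to measure was argued against, because the Cy3 signal was undetected for 3.45% of these ratios. Of the 174, 124 lay below 14.3 and 50 lay beyond it, 24 of these in DU4475 and 12 in MB157. That bound lies 2 SD over 10 if both channels spread like the reference and independently of each other. It was computed afterwards as a description. The channels had a median r of 0.599 over arrays, so that the bound may be too wide. Unequal amounts stay open. Genes that DU4475 expressed far above the other 9 lines had a median ratio of 9.48 ± 0.522, which lies within 1 SD of 10. That SD is a bootstrap over 124 genes of 1 array and is no error of the part of DU4475 in the mix. Other lines of the mix with such genes, which CAMA1 lacked, had 5.01 to 8.83. With equal parts 10 is the ceiling for such genes, and their ratio lies lower where other lines express them too. A median below or near 10 thus cannot decide. Another culture or extract in the mix than on the array may also contribute and cannot be told apart, since the interquartile range of the log2 ratio of those genes was 0.738 ± 0.0939, against a bound of 0.737 set before. Equal parts also spread these ratios below 10, which widens that range without another culture. No biological explanation was tested.

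The Cy3 signal of the common reference stood apart on 1 array for 129 genes, and for 128 of these the line on that array had the highest Cy5 signal. The tables argue against the normalization, since the unnormalized Cy3 signal of these genes was already 11.1 times that on other arrays (median). Cy5 light read in the Cy3 channel could account for it, and the Cy3 excess was 2.54% of the Cy5 signal (median of 64 pairs of gene and array), but the share varied 7.16 times between its 10th and 90th percentiles, which neither a constant share (under 3) nor a plainly variable one (over 10) covers. Single shares ran from 0.0362% to 11.8%, and 0.0384% and 1.21% were seen on the array of HCC1187 alone, which goes against a fixed share there, but a share that varies between spots stays open. RNA of the line in the Cy3 sample stays open too: 39.6% of the variance of the share lay between arrays, and 7 of 100 permutations gave as much, over 44 pairs on 10 arrays, too few to exclude it although the value lay in the range that had been set against it. Of the 128 genes 117 lay on arrays of lines outside the mix, and no biological explanation was tested.

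Histone genes rose and fell together from line to line. Slide effects were argued against, since their mean pairwise r was 0.729 with slide means removed and 0.683 before. Probes that bind several near-identical transcripts were argued against as the whole cause, because the linker histone gene H1-2, which differs in sequence from H2A and H2B genes, had r = 0.798 with their median, at the 99.84th percentile of all genes. Growth was argued against in the form tested, since the list median had r = 0.0634 (permutation p = 0.657, rho = 0.0357) with the proliferation list median, and -0.623, 0.639 and 0.0777 within the 3 largest scan days. A difference between the lines in histone transcripts that carry a poly(A) tail may remain as a hypothesis, which was not tested.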

How the results depend on the processing

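The settings of detected probes only, genes detected in Cy3 on all arrays, scan day means removed and the omission of DU4475 were chosen after the data were seen. The software's flag of dim spots was set everywhere, so no filter and the flag on all arrays gave no values of their own and were not run. No paired analysis was possible because each line had 1 array. Direction and side of the threshold held in 885 of 933 recomputed pair correlations, with 25 lost and 22 gained calls, and in 333 of 338 list coherences. Of 611 recomputed medians of lists in their highest and lowest lines, 452 moved little and 158 more. Signs turned for ESR1 with GREB1 in the lines of higher GREB1 with the mean of a gene's probes (-0.0450), for the coherence of the melanocyte list among genes detected in Cy3 on all arrays (-0.0211) and for the proliferation median of MB231 with slide means removed (-0.0027). The melanocyte filter leaves out members that the mix lacks, and the MB231 value rests on its difference to MB330, the only other line on that slide.

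Genes more variable between lines numbered 14980 with no normalization between arrays and 18259 with Gquantile in place of Aquantile, and 20 lists were coherent by Spearman's rho. The share on the first component was 21.9% with slide means removed, 22.2% with 500 genes and 13.6% with all genes, where that on the second was 6.29%. Genes set apart in 1 line numbered 164 with slide means removed, 180 among genes detected in Cy3 on all arrays, 194 without DU4475 and 84 at a gap of 3. The share of genes with a mean ratio near 1 in the mix was 64.3% with the scanner software's signals and with the deposited table, 45.1% with median centring, 67.4% with an offset of 16, 76.8% with the mean of probes, 70.0% among detected probes, 66.3% among genes detected in Cy3 on all arrays and 66.3% with the median over lines. Ratios over 10 numbered 386 with median centring and 96 without DU4475. Lines of the mix minus others came to -66.6 genes (scanner software), -80.1 (median centring), -66.0 (deposited table), -18.7 (slide means removed), -94.3 (scan day means removed) and -89.1 (without DU4475). No line had its nearest on the same slide (0) once slide means were removed, by construction. For counts, a larger gap, a subset of the genes and, for ratios over 10, the omission of DU4475 leave fewer by construction. Removing slide means takes away part of any excess of a single line and leaves out arrays alone on a slide. Of the genes set apart, 123 were so in DU4475 and 183 in other lines, which accounts for the lower count without DU4475. For the other values the cause was not tested.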

Other observations

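Some of the 123 genes set apart in DU4475 are given here, chosen after their values were seen. The kinase genes ZAP70 (3.02), BLK (3.76) and SYK (4.15), the receptor gene PDCD1 (3.11), the transcription factor gene TCF7 (3.63) and the protease gene GZMA (2.05) were at least 2 above every other line on the log2 scale there. ARHGDIB was 30.7-fold below the reference in DU4475. FREM1 (5.03), DBH (3.39) and MIAT (5.34) were set apart in the same line.

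CEACAM6 reached 4.34 in SUM190, 3.44 in SUM225 and 3.17 in HCC2218, while SPRR1B and FLG were highest in MCF12A (4.96) and MB231 (4.18). The immediate early gene EGR1 stood at least 4-fold above the reference in 17 lines, and it was highest in 184B5 (4.66), MCF10A (4.25) and MB453 (4.25). Single members of the melanocyte list were high outside MB435, the line with its highest median, since SOX10 was highest in COLO824 (3.46) and HCC2157 (2.99), and GPNMB was highest in COLO824 (3.76) and MB157 (3.76).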
